A study of Mus musculus with 12 samples.

How the data were processed

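RNA from mouse J1 embryonic stem (ES) cells was hybridised to Affymetrix mouse genome 430A 2.0 arrays, in which a set of short probes reports on each transcript. The cells were grown on gelatin in serum and leukemia inhibitory factor, per the labels' protocols. The 12 arrays fall into 6 groups of 2: a pool of cells overexpressing Arid3a (OE pool), cells labelled as high overexpression of Arid3a and as a single colony (OE high), a BirA control (BirA is a bacterial biotin ligase), an Arid3a knockdown (Arid3a KD), an Oct4 knockdown (Oct4 KD; Oct4 is the protein of Pou5f1) and a knockdown control (KD control). Groups and replicate numbers were taken from the sample titles. Whether the 2 arrays of a group came from separate cultures is not stated, so p-values measure only the spread between these samples, which may be technical.

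The deposited values are log2 intensities per probe set. They were made with RMA (background correction, quantile normalization and a summary per probe set), per the submitters' processing notes. The RMA version, the software, and whether all arrays were processed in a single run are not given in the sources used here. RMA pulls the arrays to a common distribution, so a change of most genes in one direction would be hidden. The values ran from 1.85 to 14.3 with 0 missing values among 22690 probe sets. No scanner values or detection calls were used here, so low values have no measured background, and fold changes of dim genes are compressed. For arrays the number of arrays limits the precision.

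Genes were named through the platform annotation, with symbols updated by gene identifier through a RefSeq table of assembly GRCm38.p6. Of the probe sets, 20393 had 1 gene symbol, 691 had several and 1606 had none; 20364 of those with 1 symbol matched the table. Only probe sets with 1 symbol were used. For each of 12394 genes the probe set with the highest mean over all arrays was kept (4958 genes had several). No separate step removed the 64 control probe sets of the array, so any of them annotated with 1 gene symbol could be the one kept. The build behind the array is not stated, so no coordinates are given.

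The tests used limma 3.58.1 in R 4.3.3: lmFit with a mean per group over all 12 arrays, contrasts, and eBayes with a trend of the spread on the mean level. All groups thus share 1 estimate of the spread, with 6 residual degrees of freedom and 3.98 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes in a comparison, and the count at 2-fold or more is given beside it. There were 7 comparisons: OE high and OE pool against the BirA control, Arid3a KD and Oct4 KD against the KD control, OE high against OE pool, Arid3a KD against Oct4 KD, and the BirA control against the KD control. SDs are over the 2 arrays of a group and standard errors (SE) come from limma. With 2 arrays per group, exact permutation tests cannot give small p-values.

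The lists of genes were written from textbook knowledge before the data were examined, as were the design, the rule for named genes and the other settings to be tried. The 22 lists cover pluripotency, trophectoderm and trophoblast, primitive and extraembryonic endoderm, mesendoderm and mesoderm, neural and ectoderm, primed epiblast, two-cell-like state, blood lineage, Hox genes, germline genes, fibroblast (feeder) markers, epithelial junction genes, cell cycle G2 and M, DNA replication and S phase, ribosome biogenesis and Myc targets, p53 targets, unfolded protein and amino acid stress, interferon response, glycolysis and hypoxia, cholesterol synthesis, the Arid family with Hdac partners, and readouts of Wnt, Fgf, Bmp and Nodal signalling. Of 557 genes written, 496 were measured; some genes stand in more than 1 list. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison. The same test with an estimated correlation, and fry, stood beside it. Fry asks whether the members move one way on balance and does not compare them with other genes. The correlation of a list was estimated from the residuals of all 12 arrays, so it is the same in each comparison. The spread of the Oct4 KD arrays, 64.1% of the pooled variance, thus enters it everywhere. That version also has only the 6 residual degrees of freedom, so its p-value can rise without a higher correlation.

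The text names Arid3a and Pou5f1 in each comparison. It further names genes from the 12 highest and 12 lowest log2 fold changes of each control comparison (6 and 6 in the others) among called genes whose arrays did not overlap between the groups. From each list it names 2 to 4 members by the largest absolute change among those called, or among all where none was. The markers Cdx2, Gata3, Gata4, Gata6, Nanog, Sox2 and T could also be named; T had no usable probe set. Genes named outside this rule are marked as chosen after their values were seen.

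The procedure was tested on simulated data with the real genes and each group's own spread, 200 of 12394 genes changed. For OE pool against the BirA control, 9.0% of genes changed by 0.5 on the log2 scale were recovered, 80.6% of those changed by 1 and 95.5% of those changed by 2, with 0 false calls. For OE high the shares were 14.9%, 67.2% and 93.9% with 6 false calls. For Arid3a KD they were 10.4%, 68.7% and 98.5% with 0 false calls. For Oct4 KD they were 38.8%, 76.1% and 97.0% with 333 false calls, since the shared spread is smaller than that of the Oct4 KD arrays. On unchanged simulated data camera called 0 of 22 lists for Arid3a KD, and it called a list shifted by 0.5. The genes varied independently in this single draw, while the estimated correlation of the real epithelial junction genes was 0.693. It therefore does not show how often camera calls unchanged lists whose members vary together.

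The other settings, fixed beforehand, were the mean of a gene's probe sets, each probe set on its own, the dimmest genes left out, another quantile normalization, centring of each array, only the 2 groups compared, no trend, a replicate block, a threshold of 0.01 or of 2-fold, and leaving out each array in turn. Further settings were chosen after seeing the data: leaving out the Oct4 KD arrays, using the control of the other arm, and giving 1 control array to each of 2 groups that share controls.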

Results

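The arrays measured how mouse ES cells differ in gene expression when Arid3a, an AT-rich DNA-binding transcription factor, is raised or lowered, and when the pluripotency factor Oct4 is lowered. The study's title places the work in the first cell fate decision, between embryo and extraembryonic tissue. Over 12394 genes, replicate arrays correlated at 0.999 in the OE pool, 0.994 in OE high, 0.997 in the BirA control, 0.998 in Arid3a KD, 0.977 in Oct4 KD and 0.999 in the KD control. The SD between replicates was 0.41 in Oct4 KD and between 0.098 and 0.20 in the other groups, so Oct4 KD supplied 64.1% of the pooled variance. No pair was a duplicate, with 7 to 14 probe sets of identical value. OE high replicate 2 was most similar to KD control replicate 1 (0.996), and Oct4 KD replicate 2 to OE pool replicate 2 (0.978).

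Arid3a was lower in its knockdown and higher in the Oct4 knockdown. Its only usable probe set read 6.20 ± 0.05 (SD, n = 2) in Arid3a KD against 6.81 ± 0.00 in the KD control, a 1.54-fold lower level that did not pass the test (log2 fold change -0.62 ± 0.14 SE, adjusted p = 0.0899). In Oct4 KD it read 8.04 ± 0.12, 2.34-fold above the KD control (1.22 ± 0.14, adjusted p = 0.000178). Overexpression was barely visible: the OE pool read 7.24 ± 0.13 and OE high 7.20 ± 0.17 against 6.95 ± 0.09 in the BirA control, log2 differences of 0.29 (adjusted p = 0.44) and 0.26 (adjusted p = 0.655). Whether this probe set lies in the introduced Arid3a is not given in the sources used here, so it does not check the overexpression. Pou5f1 fell 7.77-fold in Oct4 KD, to 9.65 ± 0.32 from 12.61 ± 0.03 (-2.96 ± 0.13, adjusted p = 1.1e-06). Its log2 differences of -0.17 in the OE pool (adjusted p = 0.693), -0.15 in OE high (adjusted p = 0.827) and -0.10 in Arid3a KD (adjusted p = 0.82) did not pass.

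**Figure D1:**
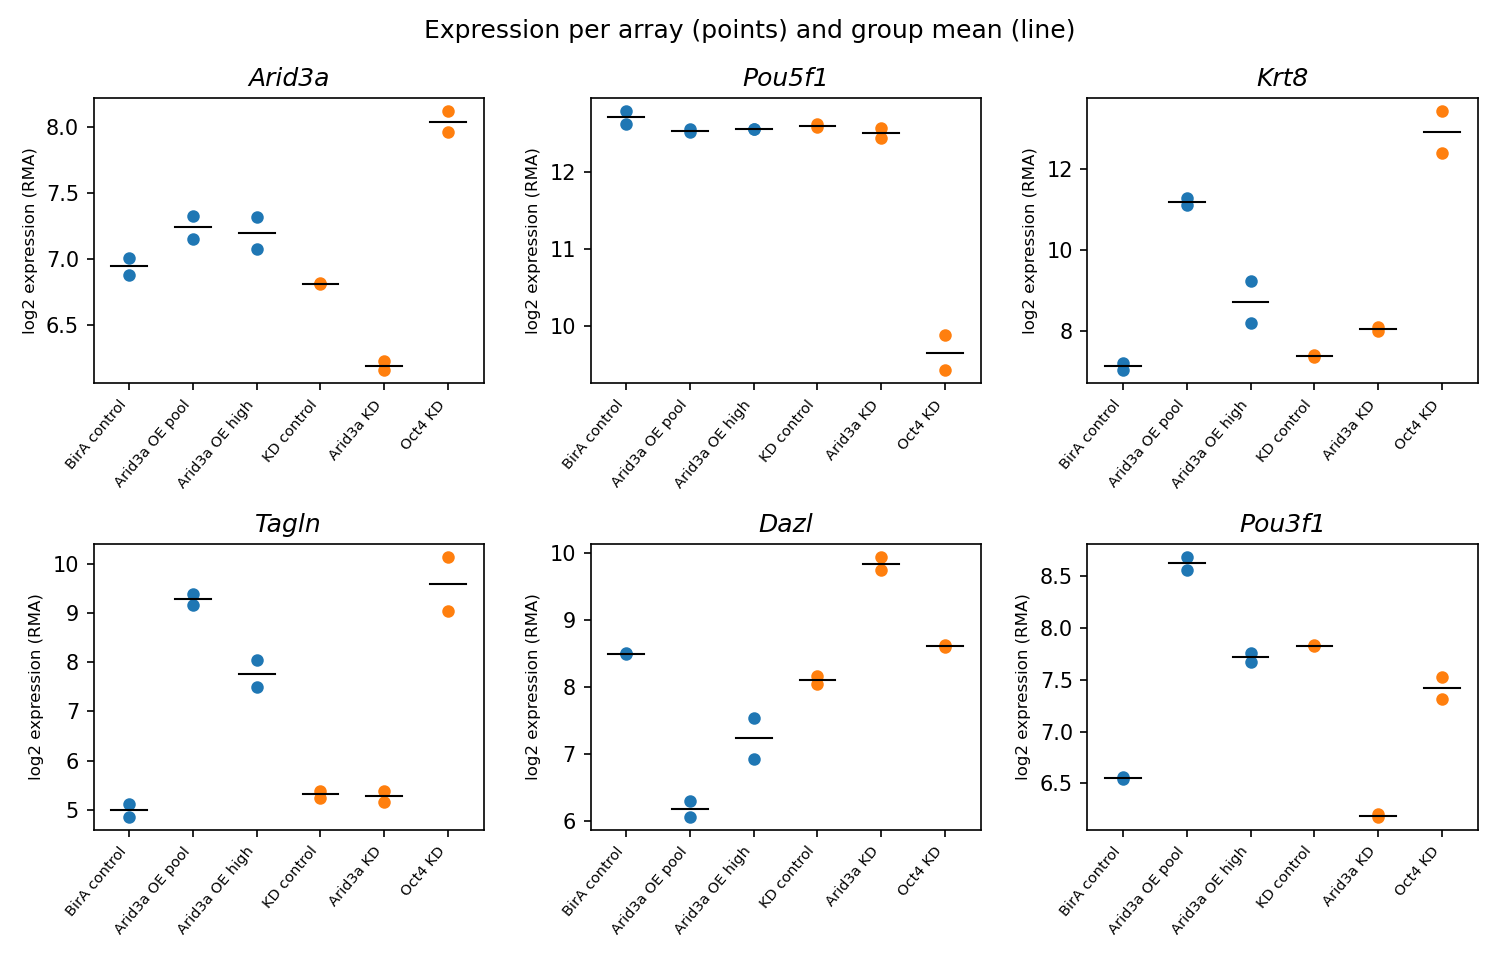
Log2 expression (RMA) of Arid3a, Pou5f1, Krt8, Tagln, Dazl and Pou3f1 on each array (points) with the group mean (line), overexpression arm in blue and knockdown arm in orange. The y axes do not start at 0. Pou5f1 is at 9.42 and 9.88 on the Oct4 KD arrays and at 12.45 or above on all others, and the control groups differ in Pou3f1 (6.55 against 7.82).

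Among the overexpression groups, the OE pool differed more from the BirA control, with keratins, the actin-binding Tagln and interferon-inducible GTPases among the largest changes. The keratins Krt8 and Krt18 rose 17.1-fold and 12.1-fold, Tagln 19.7-fold, the matrix protein Thbs1 11.8-fold, and the differentiation inhibitor Id2 8.79-fold. Gbp2b and Gbp2, interferon-inducible GTPases, rose 32.2-fold and 25.7-fold from near the bottom of the scale. The protease Prss23 (21.3-fold), the carbonic anhydrase Car4 (13.1-fold), the metal transporter Slc39a8 (12.3-fold), Fgfbp1 (10.8-fold) and Igfbp3 (9.63-fold) completed the 12 highest. The BirA control was also low for Prss23 (2.60), Slc39a8 (2.98), Thbs1 (3.19) and Car4 (4.07), so these folds may be compressed. Among the lowest were the germ cell genes Dazl (log2 fold change -2.32) and Fmr1nb (5.45-fold lower) and the meiotic cohesin Smc1b (2.65-fold), the testis genes Cyct and Catsperz (3.04-fold and 2.81-fold), Tgfbi (3.12-fold), Vegfc (2.92-fold), Smarcd3 (2.72-fold) and Fos (2.72-fold).

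Of 40 measured trophectoderm and trophoblast genes, 6 rose and 0 fell in the OE pool (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.7e-08). They were Krt8, Krt18, Krt19, Id2, Rhox6 (log2 fold change 2.31 ± 0.36) and Sfn (1.49 ± 0.15). The list's call was lost with an estimated correlation, adjusted p = 0.213. The lineage factors Cdx2 (0.63 ± 0.28, adjusted p = 0.377) and Gata3 (0.89 ± 0.22, adjusted p = 0.0805) did not pass. Epithelial junction genes rose in 6 of 21 (12 adjusted over the list alone, camera adjusted p = 1.09e-13, and adjusted p = 0.247 with an estimated correlation). Among these 6 were Krt8, Krt18 and Krt19, which also stand in the trophectoderm list. The others were Ap1m2 (1.65), the splicing factor Esrp1 (1.44 ± 0.15) and the epithelial factor Grhl2 (1.06 ± 0.13). Fibroblast markers split, 4 higher and 3 lower of 23 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00198, adjusted p = 0.426 with an estimated correlation): Tagln, Thbs1, Acta2 (2.39 ± 0.25) and Ccn2 (1.69 ± 0.26) rose, while Tgfbi, Thy1 (-1.11 ± 0.24) and Vim (-0.84 ± 0.11) fell. The fibroblast collagen Col1a1, chosen after its values were seen, lay between 4.07 and 4.72 on the OE pool and BirA control arrays.

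Among the called lists, 3 held with both correlations in the OE pool. With fry these 3 passed too, as did trophectoderm genes (adjusted p = 0.0351), epithelial junction genes (adjusted p = 0.0351) and germline genes (adjusted p = 0.00573). Fibroblast markers (adjusted p = 0.111), pluripotency genes (adjusted p = 0.234) and glycolysis and hypoxia genes (adjusted p = 0.635) did not pass with fry. Primed epiblast genes rose in 5 of 16 (7 adjusted over the list alone), among them the POU factor Pou3f1 (2.07 ± 0.13) and Igfbp3 (3.27 ± 0.22); camera gave adjusted p = 7.55e-07, and adjusted p = 0.0159 with an estimated correlation. The list median was 0.26, and 0.15 against the KD control (camera adjusted p = 0.0415 at the preset correlation). Interferon response genes rose in 3 of 22 (7 adjusted over the list alone): Gbp2, the immunoproteasome subunit Psmb8 (2.64 ± 0.37) and Cxcl10 (1.38 ± 0.27; camera adjusted p = 2.48e-06, adjusted p = 0.0159 with an estimated correlation). Cholesterol synthesis genes had 0 members called either over all genes or adjusted over the list alone, with a list median of -0.31 (camera adjusted p = 0.000176, adjusted p = 0.0333 with an estimated correlation). Germline genes fell in 2 of 14 (6 fell and 1 rose adjusted over the list alone), Dazl and Tex11 (-0.82 ± 0.17), with camera adjusted p = 0.000321 and adjusted p = 0.057 with an estimated correlation. Pluripotency genes gave 1 higher, Dppa3 (2.47 ± 0.42), and 1 lower, Upp1 (-0.87 ± 0.16), of 35 (1 and 4 adjusted over the list alone; list median -0.09, camera adjusted p = 0.0144, adjusted p = 0.518 with an estimated correlation). The call also ended without BirA control replicate 2. Glycolysis and hypoxia genes had 0 of 24 called, also adjusted over the list alone (list median -0.19, camera adjusted p = 0.0249, adjusted p = 0.795 with an estimated correlation). The call was lost without BirA control replicate 2, and the median had the other direction against the KD control (0.24, adjusted p = 0.0749).

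In all, 285 genes were called in the OE pool against the BirA control, 206 higher and 79 lower. Of these, 155 changed by 2-fold or more. The count was 78 without OE pool replicate 1, 71 without replicate 2, 77 without BirA control replicate 1 and 93 without replicate 2, and 1525 without the Oct4 KD arrays, a setting in which the BirA control against the KD control gave 1312. Against the KD control 329 genes were called, 164 of them among the 285. All of the 12 highest genes stayed called there, with Id2 at a smaller log2 fold change of 1.79, and of the 12 lowest 8 did; Fos, Cyct, Calb2 and Smc1b did not.

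OE high shared Tagln, Acta2 and Krt18 with the OE pool, and the stress factor Ddit3 rose. Krt8 and Krt19 were not called in OE high, although Krt8 read 9.23 and 8.19 there against 7.02 and 7.21 in the BirA control. Tagln rose 6.91-fold, Acta2 5.93-fold, Id2 5.38-fold, Prss23 5.10-fold, Thbs1 3.32-fold and Krt18 2.98-fold. The AP-1 subunit Jun rose 3.92-fold, the endocytic receptor Lrp2 3.29-fold, the sulfotransferase Hs6st2 2.88-fold, the stress factor Ddit3 2.85-fold, the kinase Pim2 2.79-fold and 2610528J11Rik 3.41-fold. The 6 genes that fell were Dazl (2.41-fold), Serpinb1a (2.24-fold), Fos (1.96-fold), Rcn1 (1.88-fold), Catsperz (1.85-fold) and the fatty acid oxidation enzyme Acaa2 (1.66-fold).

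Unfolded protein and amino acid stress genes were higher as a list in OE high, with a median of 0.40 over 24 genes (camera adjusted p = 8.25e-09, adjusted p = 0.0181 with an estimated correlation); 1 member, Ddit3, passed over all genes and 8 adjusted over the list alone. Cholesterol synthesis genes were lower, with a median of -0.35, 0 of 16 called over all genes and 3 lower adjusted over the list alone (camera adjusted p = 3.77e-07, adjusted p = 0.0181 with an estimated correlation). Primed epiblast genes had 1 of 16 called, Pou3f1 (1.16 ± 0.13), 6 adjusted over the list alone and a list median of 0.19 (camera adjusted p = 0.00078, adjusted p = 0.0476 with an estimated correlation). Against the KD control the median was -0.07 (adjusted p = 0.771), and Pou3f1 lost its call and its direction (-0.11, adjusted p = 0.792). Trophectoderm genes had 2 of 40 called, Id2 and Krt18, and 3 adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.918 with an estimated correlation). That list was no longer called without OE high replicate 1 or BirA control replicate 1. Epithelial junction genes had 2 of 21 called, Krt18 and Esrp1 (1.24 ± 0.15), and 6 adjusted over the list alone (camera adjusted p = 2.52e-07, adjusted p = 0.717 with an estimated correlation). Interferon response genes had 0 of 22 called, also adjusted over the list alone (camera adjusted p = 0.0279, adjusted p = 0.143 with an estimated correlation). This call ended without OE high replicate 1 or either BirA control array; Gbp2 read 6.60 on OE high replicate 1 and 3.49 on replicate 2. Among fibroblast markers 3 of 23 rose, Tagln, Acta2 and Thbs1, and the list did not pass (camera adjusted p = 0.128). With fry, trophectoderm genes (adjusted p = 0.539) and epithelial junction genes (adjusted p = 0.405) did not pass, and the other lists called by camera did.

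The comparison of OE high with the BirA control called 48 genes, 42 higher and 6 lower, 31 by 2-fold or more. The count was 21 without OE high replicate 1, 73 without replicate 2, 2 without BirA control replicate 1 and 3 without replicate 2, and 820 without the Oct4 KD arrays, a setting that called 1312 genes between the control groups. With either OE high array left out, many of the genes called were not among the 48. Against the KD control 68 genes were called, 22 of them among the 48. Of the 12 highest 8 stayed called, without Id2, 2610528J11Rik, Lrp2 and Hs6st2, and of the 6 lowest only Rcn1 and Catsperz. Jun stayed called at a smaller log2 fold change of 1.17, and Fos turned to the other direction (0.43, adjusted p = 0.286).

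OE high and the OE pool differed directly in stress genes and in Krt8 and Krt18. Stress genes were higher in OE high: Nupr1 (3.86-fold), Ddit3 (3.71-fold) and the glutathione-degrading Chac1 (3.54-fold), along with the GABA-synthesising Gad1 (3.51-fold), Lcorl (2.93-fold) and Cpn1 (2.85-fold). Krt8 (5.64-fold), the small heat shock protein Cryab (5.30-fold), Igfbp3 (4.83-fold), Efemp1 (4.72-fold), Anxa3 (4.33-fold) and Prss23 (4.18-fold) were lower in OE high. Arid3a (-0.04, adjusted p = 0.978) and Pou5f1 (0.02, adjusted p = 0.987) did not pass. In this direct contrast 69 genes were called, 33 higher and 36 lower in OE high, 37 by 2-fold or more. The count was 12 without OE pool replicate 1, 8 without OE pool replicate 2, 45 without OE high replicate 2 and 936 without the Oct4 KD arrays. Trophectoderm genes fell in 3 of 40 (6 adjusted over the list alone; camera adjusted p = 3.61e-06, adjusted p = 0.374 with an estimated correlation): Krt8, Krt18 and Sfn. Epithelial junction genes fell in 2 of 21, Krt8 and Krt18 (5 adjusted over the list alone; camera adjusted p = 2.91e-06, adjusted p = 0.731 with an estimated correlation). Genes of cell cycle G2 and M had 0 of 25 called, 2 adjusted over the list alone and a median of 0.10 (camera adjusted p = 0.0386, adjusted p = 0.78 with an estimated correlation). The call was lost without either OE pool array or OE high replicate 1. Stress genes (median 0.44, adjusted p = 0.0145 with an estimated correlation) and germline genes (0.54, adjusted p = 0.0324) were higher in OE high. Interferon response genes (-0.13) and primed epiblast genes (-0.14) were lower, both at adjusted p = 0.0385 with an estimated correlation.

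Across genes, the fold changes of OE high and the OE pool against their shared BirA control correlated with r = 0.65 and rho = 0.53; genes are not independent replicates. Unchanged groups simulated against the same controls gave r = 0.46, and the covariance was 0.055 against a simulated 0.0097. Among called genes, 29 were higher in both (0.70 from independent lists), including Tagln, Id2, Prss23 and Thbs1, 5 were lower in both (0.04), including Dazl and Fos, and 0 went in opposite directions. Counts from independent lists are a rough guide here and below. All comparisons share 1 spread per gene, so genes of small spread are called more readily in each. With 1 BirA control array given to each group, r was 0.53 or 0.44 and the covariance 0.049 or 0.043, depending on which array went to which group, so part of the correlation goes with the shared controls. Those fits called 2 or 3 genes in OE high, all higher in both groups.

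In Arid3a KD, epithelial, germ cell and several other genes were higher than in the KD control, and Myc and neural or epiblast transcription factors were lower. Most of the lower genes lost their call against the BirA control. The highest were Epb41l5, a FERM-domain protein of epithelial polarity (4.07-fold), the phospholipase Pla2g4a (4.03-fold), Krt19 (3.94-fold), Serpinb5 (3.57-fold), 1700018B24Rik (3.50-fold), Dazl (3.33-fold), the cathepsin Ctsh (2.99-fold), the Polycomb-related Scml2 (2.94-fold), Pzp (2.87-fold), the stress-induced Ddit4 (2.62-fold), Calml4 (2.59-fold) and the epithelial sorting adaptor Ap1m2 (2.48-fold). The lowest were the neuronal intermediate filament Ina (3.58-fold lower), Map2k5 (3.44-fold), Cachd1 (3.22-fold), Myc (3.14-fold), Pou3f1 (3.10-fold), the homeobox factor Gbx2 (3.06-fold), the actin-severing Cfl2 (2.95-fold), Crmp1 (2.66-fold), Purb (2.52-fold), Zfp936 (2.49-fold), Zic2 (2.47-fold) and Bcl11a (2.40-fold). Cdx2 (-0.02, adjusted p = 0.982), Nanog (0.40, adjusted p = 0.396) and Sox2 (0.18, adjusted p = 0.581) did not pass.

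Against the BirA control, 9 of the 12 highest genes stayed called, and Krt19 (1.02, adjusted p = 0.407), Ctsh (1.05, adjusted p = 0.256) and Ddit4 (0.41, adjusted p = 0.53) did not. Of the 12 lowest only Map2k5 (-1.66, adjusted p = 0.00734) and Cfl2 (-1.29, adjusted p = 0.00173) stayed called. Ina (-0.14), Myc (-0.38), Pou3f1 (-0.36), Gbx2 (-0.26) and Zic2 (-0.20) lay close to the BirA control, and Bcl11a lay above it (0.37). Ina read 7.47 and 7.42 in the BirA control, 7.47 and 7.13 in Arid3a KD, 9.11 and 9.17 in the KD control, and 8.84 to 9.36 on the overexpression arrays. Exchanging the controls does not show which control group was shifted.

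Camera called 10 of 22 lists in Arid3a KD, of which 0 held with an estimated correlation. With fry, germline genes (adjusted p = 0.00302) and primed epiblast genes (adjusted p = 0.00108) passed, and the other called lists did not. Germline genes rose in 2 of 14, Dazl and Taf7l (1.19 ± 0.18; 4 adjusted over the list alone; camera adjusted p = 1.37e-06, adjusted p = 0.0604 with an estimated correlation). Epithelial junction genes rose in 2 of 21, Krt19 and Ap1m2 (5 adjusted over the list alone; camera adjusted p = 3.72e-06, adjusted p = 0.507 with an estimated correlation), and trophectoderm genes in 1 of 40, Krt19 (3 adjusted over the list alone; camera adjusted p = 0.0132, adjusted p = 0.536 with an estimated correlation). Primed epiblast genes fell in 2 of 16, Pou3f1 and Zic2 (8 adjusted over the list alone; median -0.35, camera adjusted p = 0.000305, adjusted p = 0.0611 with an estimated correlation). Against the BirA control the median was -0.11 (adjusted p = 0.785). Ribosome biogenesis and Myc targets had 1 of 25 lower, Myc itself, also adjusted over the list alone (camera adjusted p = 0.000279, adjusted p = 0.507 with an estimated correlation). The p53 targets (list median 0.56, camera adjusted p = 2.03e-08) and the glycolysis and hypoxia genes (0.50, camera adjusted p = 1.75e-09) had 0 members called over all genes, and 10 of 21 and 6 of 24 higher adjusted over the list alone. Both gave adjusted p = 0.363 with an estimated correlation. The control groups differed in the same lists. The BirA control lay below the KD control by a median of -0.18 in ribosome biogenesis and Myc targets (camera adjusted p = 0.000161), against -0.23 for Arid3a KD. It lay above the KD control by a median of 0.31 in p53 targets and 0.39 in glycolysis and hypoxia genes. All 3 differences between the controls were lost at adjusted p = 0.513 with an estimated correlation. Neural and ectoderm genes fell in 1 of 25, Gbx2, also adjusted over the list alone (camera adjusted p = 0.0274, adjusted p = 0.507 with an estimated correlation). That list was no longer called without Arid3a KD replicate 1 or KD control replicate 1. DNA replication genes had 0 of 23 called and 3 lower adjusted over the list alone (camera adjusted p = 0.0416, adjusted p = 0.536 with an estimated correlation). This call ended with any 1 of the 4 arrays left out. The Arid family list had 0 of 20 called and 1 lower adjusted over the list alone (camera adjusted p = 0.0442, adjusted p = 0.507 with an estimated correlation). The call was lost without Arid3a KD replicate 2 or either KD control array.

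For Arid3a KD against the KD control, 79 genes were called, 45 higher and 34 lower, 53 by 2-fold or more. The count was 9 without Arid3a KD replicate 1, 7 without replicate 2, 3 without KD control replicate 1 and 9 without replicate 2. It was 1841 without the Oct4 KD arrays, where the control groups differed by 1312 genes, and 42 against the BirA control, 24 of them among the 79.

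Against their controls, the OE pool and Arid3a KD differed in opposite directions in a few genes, the germ cell gene Dazl among them. Some epithelial genes differed in the same direction. Arid3a itself was called in neither group. Dazl was lower in the OE pool and higher in Arid3a KD, as were 1700018B24Rik (-1.14 and 1.81), Pzp (-0.78 and 1.52) and Tktl1 (-1.17 and 1.08), and these 4 kept both directions past the threshold with the controls exchanged. Krt19 (2.00 and 1.98), Epb41l5 (1.77 and 2.02), Ap1m2 (1.65 and 1.31) and Klhl13 (0.84 and 1.18) rose in both, although Krt19 did not pass in Arid3a KD against the BirA control, and Zeb1, a repressor of epithelial genes, fell in both (-0.77 and -0.82). Pou3f1 and Fos were called in opposite directions, but both also differed between the control groups. With the controls exchanged Fos had log2 differences of -0.04 in the OE pool and -0.51 in Arid3a KD, and Pou3f1 of 0.80 and -0.36. Myh3, Plaat3 and Ppp1r11 were also called in opposite directions, and with the controls exchanged they passed in neither group. Several of these genes were chosen after their values were seen, because they are the called overlap.

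Between the OE pool and Arid3a KD, 9 genes were called in opposite directions (0.85 from independent lists) and 5 in the same direction (0.96). Both overlaps lay above those counts, which ignore that genes of small spread are called more readily in both comparisons. Among the opposite calls, only Dazl, 1700018B24Rik, Pzp and Tktl1 held in both groups with the controls exchanged. Across genes r was -0.10 and rho -0.14, and r was -0.02 with the controls exchanged. For OE high, 3 genes were opposite (0.14) and 3 the same, Dpys, Gad1 and Klhl13 (0.17), with r = -0.06 and rho = -0.03; r was -0.34 without OE high replicate 1 and 0.21 without replicate 2. None of the opposite OE high calls, of Dazl, Fos and Pou3f1, held against the KD control (-0.88, 0.43 and -0.11; adjusted p = 0.0887, 0.286 and 0.792).

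**Figure D2:**
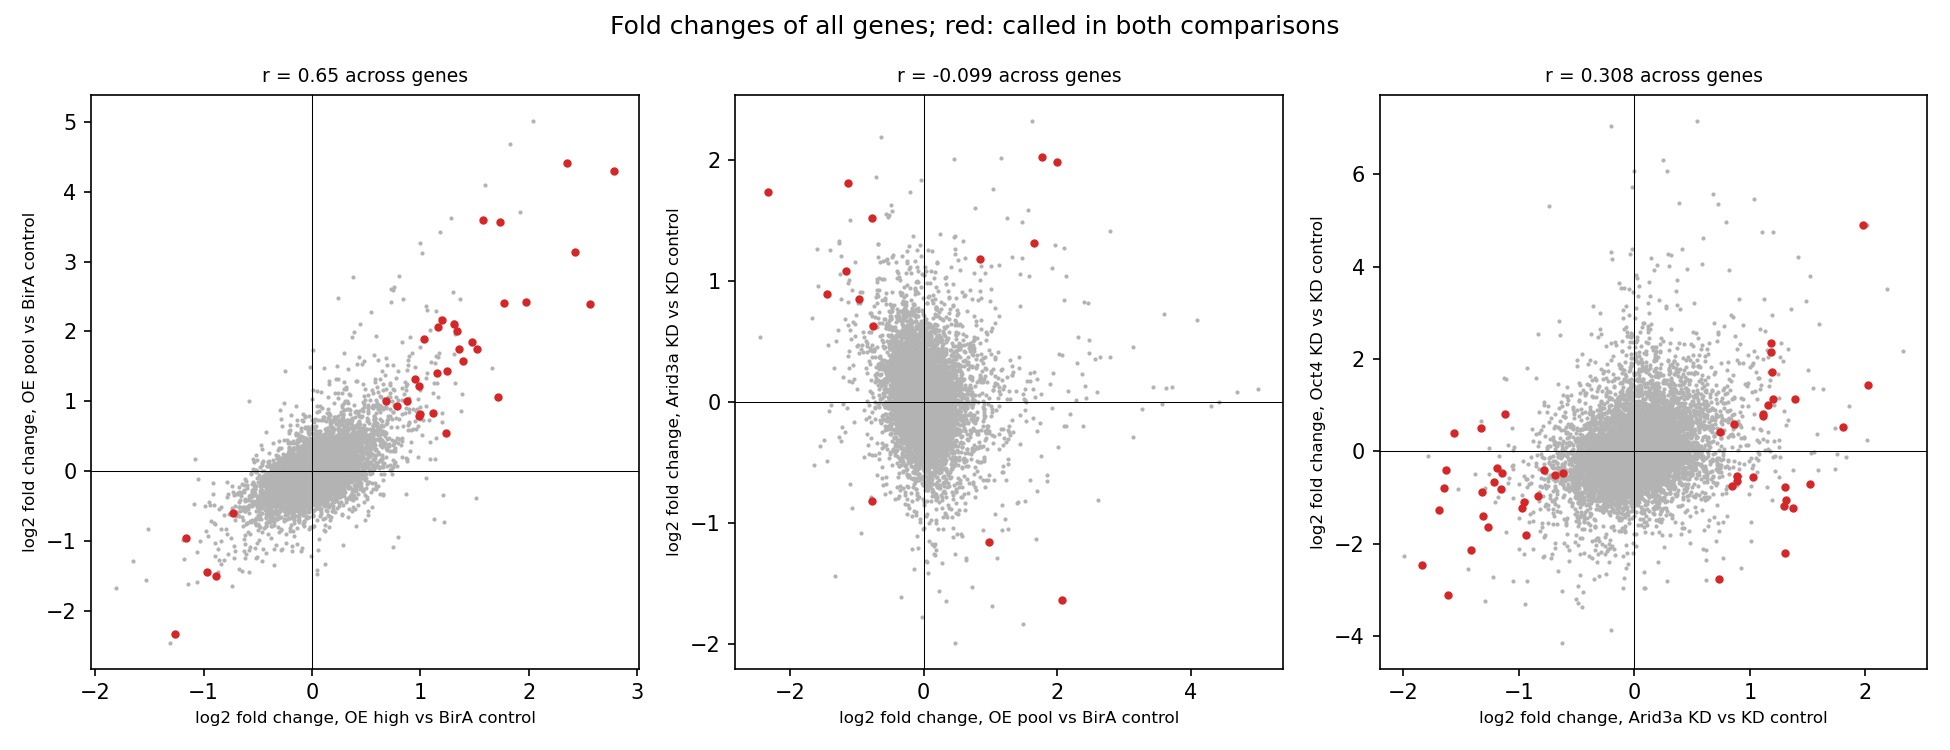
Log2 fold changes of 12394 genes in pairs of comparisons (each point a gene, red where called in both). Left, OE high against the OE pool, r = 0.65, with all 34 shared calls in the same direction in both; centre, the OE pool against Arid3a KD, r = -0.10, with 9 opposite and 5 same calls; right, Arid3a KD against Oct4 KD, r = 0.31, with 33 same and 14 opposite calls.

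Lowering Oct4 raised trophoblast genes and lowered pluripotency genes. The X-linked homeobox genes Rhox6 and Rhox9 rose 142-fold and 78.9-fold, the growth factor Igf2 132-fold, Bhmt 67.4-fold, Vnn1 67.0-fold, the placental gene Plac1 53.1-fold, Krt8 47.4-fold, Nrk 44.1-fold, Pmp22 41.7-fold, Krt18 41.2-fold, the placental imprinted gene Sfmbt2 39.6-fold and Parm1 31.2-fold. Several of these differed between the 2 Oct4 KD arrays by enough that leaving out either moves the fold by more than 1.5 times: Plac1 (SD 2.45), Vnn1 (1.16), Rhox9 (1.11), Nrk (1.00), Rhox6 (0.94) and Bhmt (0.87), and among the lowest Mcf2 (0.97) and Pdgfc (0.95). Plac1 read 11.60 and 8.13, and Vnn1 9.87 and 8.22. The KD control read 3.60 for Rhox6, 3.79 for Rhox9, 3.88 for Bhmt and 2.98 for Vnn1. These values are low on the scale, so the folds may be compressed. Cdx2 rose 20.9-fold (to 9.22 ± 0.78 from 4.83 ± 0.12) and Gata3 11.5-fold, Gata6 rose 6.53-fold, and Gata4 did not pass (-0.20, adjusted p = 0.436). Besides Pou5f1, the lowest were Mcf2 (17.6-fold), Ephx2 (14.5-fold), the chromatin remodelling genes Smarca1 (10.3-fold) and Smarcd3 (9.72-fold), the pluripotency gene Nr0b1 (9.81-fold), Pdgfc (9.42-fold), Myb (9.15-fold), Gbx2 (8.62-fold), 1700097N02Rik (8.20-fold), Fhod3 (8.14-fold) and Pdcl2 (7.75-fold). Nanog (1.61-fold, adjusted p = 0.0244) and Sox2 (1.49-fold, adjusted p = 0.00593) fell less.

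Camera called 8 of 22 lists in Oct4 KD, of which 0 held with an estimated correlation. With fry the p53 targets did not pass (adjusted p = 0.0559), and the other called lists did, epithelial junction genes narrowly (adjusted p = 0.0495). Fry does not compare members with other genes, and 29.9% of all genes were called here. Of 40 trophectoderm and trophoblast genes 30 rose and 1 fell, the same adjusted over the list alone. The list median was 1.99 (camera adjusted p = 2.14e-18, adjusted p = 0.204 with an estimated correlation, fry adjusted p = 0.000244). Of 35 pluripotency genes 23 fell, including Tcl1 (-2.78 ± 0.18) and Klf2 (-2.38 ± 0.13), and 2 rose (26 and 2 adjusted over the list alone; camera adjusted p = 2.54e-06, adjusted p = 0.319 with an estimated correlation). Primitive and extraembryonic endoderm genes rose in 13 of 33 and fell in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 0.000145, adjusted p = 0.529 with an estimated correlation), with the basement membrane collagens Col4a1 (4.61 ± 0.28) and Col4a2 (4.27 ± 0.36) and Cited1 (4.15 ± 0.29). Fibroblast markers rose in 13 of 23 (the same adjusted over the list alone; camera adjusted p = 1.42e-06, adjusted p = 0.319 with an estimated correlation), led by Acta2 (4.31 ± 0.25), Tagln (4.28 ± 0.31) and Thbs1 (3.46 ± 0.25). Col1a1 read 4.97 and 4.40 on the Oct4 KD arrays. Epithelial junction genes rose in 9 of 21 and fell in 3 (12 and 5 adjusted over the list alone; camera adjusted p = 0.00257, adjusted p = 0.746 with an estimated correlation). That list was no longer called without Oct4 KD replicate 1. DNA replication genes fell in 14 of 23 and rose in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 1e-04, adjusted p = 0.43 with an estimated correlation), with Tk1 at -1.05 ± 0.16 and Tyms, the riser, at 1.76 ± 0.16. Ribosome biogenesis and Myc targets fell in 13 of 25 (14 adjusted over the list alone; camera adjusted p = 0.000844, adjusted p = 0.575 with an estimated correlation), among them Polr1b (-0.91 ± 0.17). The p53 targets rose in 10 of 21 and fell in 3 (11 and 5 adjusted over the list alone; camera adjusted p = 0.0124, adjusted p = 0.746 with an estimated correlation), with Perp at 2.34 ± 0.49, a call lost without Oct4 KD replicate 2.

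For Oct4 KD against the KD control, 3706 genes were called, 1581 higher and 2125 lower, 1214 by 2-fold or more. Simulated data with each group's own spread and only 200 changed genes gave 333 false calls here. The adjusted threshold depends on how many genes change, so this count cannot be read as a share of the 3706. A fit of the 2 groups alone called 523 genes, 522 of them among the 3706. The count was 6044 without Oct4 KD replicate 2, 1899 without KD control replicate 1 and 1912 without KD control replicate 2. The array's own Actb control probe sets differed between their 3-prime and 5-prime ends by 0.83 on Oct4 KD replicate 1 and by 0.55 on replicate 2, against 0.77 to 0.88 on the other arrays. For the Gapdh control the values were 0.15 on replicate 1 and 0.14 on replicate 2.

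The 2 knockdowns overlapped in part. Called in both and in the same direction were 33 genes, 13 higher (5.74 from independent lists) and 20 lower (5.83), among them Krt19, Ddit4, Gbx2, Myc and Pou3f1; 14 genes went in opposite directions (12.05). Across genes r was 0.31 and rho 0.30, against 0.18 for simulated unchanged groups with the same controls, and the covariance was 0.064 against a simulated 0.0057; r was 0.19 without Oct4 KD replicate 1. With 1 KD control array given to each knockdown, r was 0.28 or 0.27 and the covariance 0.060 or 0.057; the called overlap could not be repeated, since Arid3a KD then had 9 or 3 calls. A level common to both KD control arrays is not removed in this way, and Gbx2, Myc and Pou3f1 lost their Arid3a KD calls against the BirA control. Directly compared, Arid3a KD held higher Ephx2 (12.6-fold), Mcf2 (11.4-fold), Gpx2 (11.3-fold), Dpys (11.2-fold), Crabp1 (10.9-fold), Tcl1 (10.6-fold) and Pou5f1 (7.26-fold). It held lower Igf2 (152-fold), Rhox6 (97.6-fold), Bhmt (67.5-fold), Rhox9 (66.5-fold), Sfmbt2 (66.1-fold), Vnn1 (55.1-fold), Cdx2 (21.3-fold) and Arid3a (3.59-fold). The folds of Mcf2, Rhox6, Bhmt, Rhox9 and Vnn1 rest on Oct4 KD arrays that differ from each other. In that contrast 3580 genes were called, 2083 higher and 1497 lower in Arid3a KD, 1169 by 2-fold or more. The fit of the 2 groups alone called 596, and the count was 2023 without Arid3a KD replicate 1, 1874 without Arid3a KD replicate 2 and 5714 without Oct4 KD replicate 2. Of the trophectoderm genes 28 of 40 were lower in Arid3a KD (30 adjusted over the list alone; camera adjusted p = 4.7e-16, adjusted p = 0.276 with an estimated correlation), and 23 of 35 pluripotency genes were higher and 3 lower (25 and 3 adjusted over the list alone; camera adjusted p = 9.39e-07, adjusted p = 0.329 with an estimated correlation). Fibroblast markers had 10 lower and 1 higher, and germline genes 7 higher and 1 lower, the same adjusted over the list alone. Both gave adjusted p = 0.329 with an estimated correlation. Primitive endoderm genes had 13 lower and 4 higher (13 and 5 adjusted over the list alone; adjusted p = 0.634 with an estimated correlation). Cell cycle G2 and M had 11 higher and 1 lower, the same adjusted over the list alone, and DNA replication genes 11 higher and 2 lower (12 and 2 adjusted over the list alone). Both gave adjusted p = 0.672 with an estimated correlation. Glycolysis and hypoxia genes had 15 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.77 with an estimated correlation). The germline call was lost without either Oct4 KD array, the cell cycle call without Oct4 KD replicate 1 and the glycolysis call without Oct4 KD replicate 2.

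The BirA and KD control groups differed in 6 genes: Fos (2.65-fold) and Grcc10 (1.75-fold) were higher in the BirA control, and the interferon-inducible Irgm1 (4.10-fold), Bcl11a (3.10-fold), Pou3f1 (2.42-fold) and the Wnt inhibitor Sfrp2 (2.12-fold) were lower. With each array centred, 2 were higher and 7 lower. Arid3a (0.13, adjusted p = 0.798) and Pou5f1 (0.11, adjusted p = 0.821) did not pass. All 6 calls ended on leaving out any of the 4 arrays, each of which left 0 genes. With all arrays, 1474 genes had an unadjusted p under 0.05. The count of called genes was 2124 in a fit of these 2 groups alone and 1312 without the Oct4 KD arrays. Primed epiblast genes lay lower in the BirA control (median -0.49), with 1 of 16 called and 5 adjusted over the list alone (camera adjusted p = 9.48e-05, adjusted p = 0.0803 with an estimated correlation). A further 5 lists were called at the preset correlation and lost with an estimated correlation, each at adjusted p = 0.513: cell cycle G2 and M, ribosome biogenesis and Myc targets, p53 targets, glycolysis and hypoxia, and signalling readouts, the last also lost without either BirA control array or KD control replicate 1. The mesendoderm, two-cell-like, blood and Hox lists passed in 0 of the 7 comparisons.

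**Figure D3:**
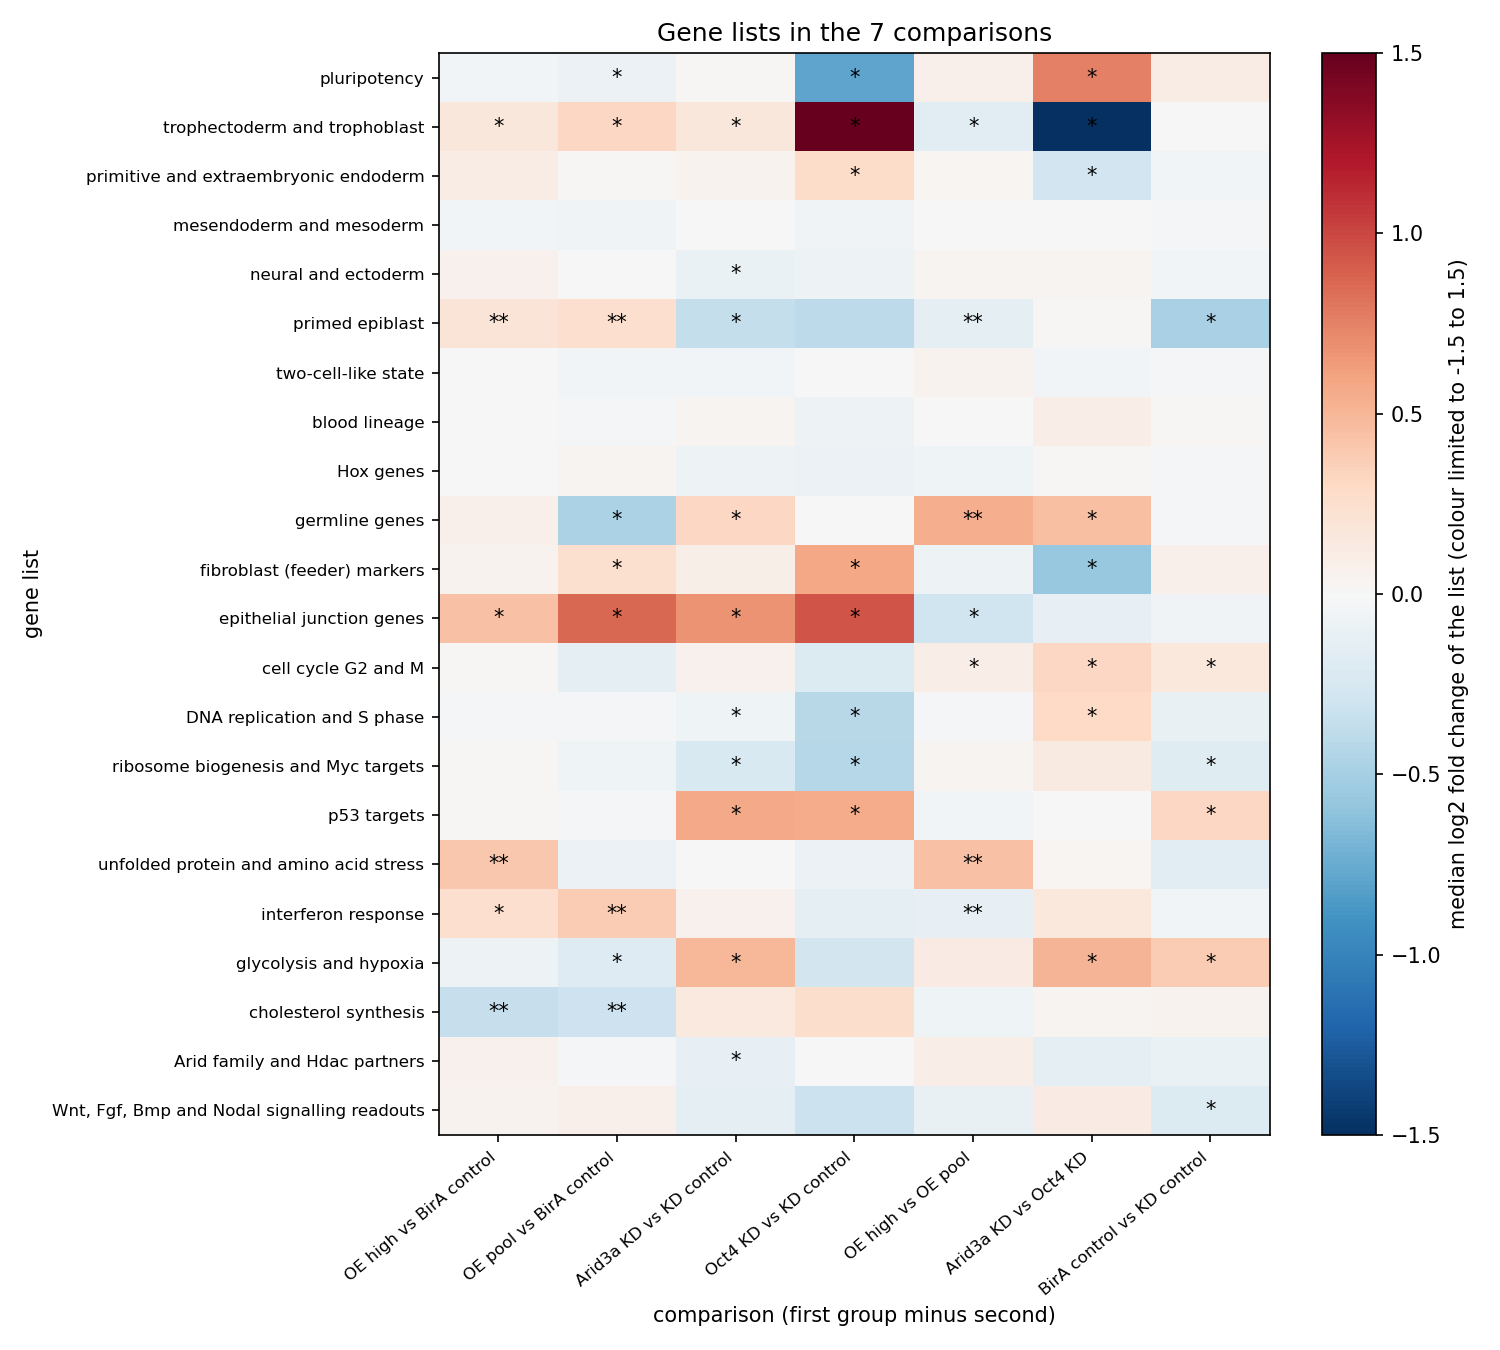
Median log2 fold change of 22 gene lists in 7 comparisons (colour, limited to between -1.5 and 1.5), with 1 asterisk where camera's adjusted p was under 0.05 at the preset correlation and 2 where it also was with an estimated correlation. The trophectoderm list reaches the colour limits in Oct4 KD (median 1.99) and in Arid3a KD against Oct4 KD (-1.72), and paired asterisks stand in 3 lists of OE high, 3 of the OE pool and 4 of OE high against the OE pool.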

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

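All tests of explanations in this part were chosen only after the results were seen. Several were also changed after an exploratory run had shown their outcome, and the first versions are given beside the later ones.

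OE high and the OE pool, each set against the BirA control, differed in 69 genes by a direct contrast in limma. As lists, 4 differed with both the preset and the estimated correlation. Unfolded protein and amino acid stress genes were higher in OE high by a median of 0.441 (3 of 24 members called: Ddit3, Chac1 and Trib3). Germline genes were higher by a median of 0.543 (Dazl and Tex14). Interferon response genes were lower, with a median of -0.125 and 0 members called. Primed epiblast genes were lower too, with a median of -0.138 and 2 called (Igfbp3 and Pou3f1). The estimated-correlation p-values were 0.0145, 0.0324, 0.0385 and 0.0385 in that order. No explanation of these differences was tested.

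Primed epiblast genes were higher in both overexpression groups and lower in Arid3a KD, each against its own control, while the controls themselves differed. With an estimated correlation the Arid3a KD call (adjusted p = 0.0611) and the difference between the controls (adjusted p = 0.0803) were lost. The list's estimated correlation was -0.012, under the preset 0.01, so correlation among its genes does not account for these losses. That version of the test has only the 6 residual degrees of freedom. A response of the list to the Arid3a level stays open. Only 1 of 16 genes, Dnmt3b, lay above all control arrays on all 4 overexpression arrays and below them on both Arid3a KD arrays, where at least 8 had been asked for and 2 or fewer were to exclude it. That test was dropped after this count was seen and has been put back, but it decides nothing. Because the controls differ, a shift of every gene by the observed medians would have carried only 3 of the 16 past all control arrays. For OE high, the values go with a low BirA control relative to the KD control, without showing which of them was shifted: against the KD control the list median was -0.065, from -0.216 to 0.032 over the 4 pairs of arrays. For the OE pool this is argued against as the whole cause, since the median fell from 0.257 to 0.146 and stayed above 0 in all pairs (0.105 to 0.22), with camera adjusted p = 0.0415. That p-value is at the preset correlation, and the version with an estimated correlation was not run against the KD control. Part of it goes with the controls. For Arid3a KD it stays open. The median was -0.354 before and -0.111 after the exchange, below 0 in all 4 pairs (-0.192 to -0.077), and the call ended because the difference shrank. The first version of this test took the groups together and would have excluded the controls as the cause with Arid3a KD at -0.1 or below and the OE pool at 0.1 or above. Both medians met those bounds, but the Arid3a KD pairs lay on both sides of -0.1, so it decides nothing there.

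The 2 OE high arrays differed from each other, and replicate 2 was nearest to the knockdown controls. RNA quality stays open. The 3-prime to 5-prime difference of the Actb control differed by 0.0215 between the 2 arrays, more than in 3 other replicate pairs outside Oct4 KD and less than in the BirA control pair (0.0345), whose transferrin receptor values also differ. A smaller value than in any 1 of these pairs was first taken to exclude it, and that bound was dropped because the single larger pair is no clean reference. The Gapdh control differed between its ends by 0.196 and 0.215 on the OE high arrays. These lay closer together than in the OE pool (0.095 and 0.128) and further apart than in the BirA control (0.071 and 0.074). Admixture of knockdown control RNA in replicate 2 stays open. The first version of the test used 39 genes called in OE high and above all controls on both arrays. Of these, 43.6% were as high or higher on replicate 2, above the 25% that was to exclude admixture. The gene set was replaced after that value was seen, because genes called from both arrays are picked for agreement between them. Of 157 genes called higher in the OE pool and above all controls on replicate 1, 18.5% were as high or higher on replicate 2, between the bounds of 10% and 25%. This set is picked for high values on replicate 1, so neither set decides. On replicate 2, 2 of 12394 genes lay 2-fold outside the span of replicate 1 and the KD control, against 64 for replicate 1. The same count, for each array against its partner and the KD control, ran from 0 to 2 in the OE pool, the BirA control and Arid3a KD. A count of 2 therefore does not single out replicate 2, and replicate 1 is the array that stands apart here. Separate colonies behind the 2 arrays stay open as well. A count of 1 gene (Uty, chosen after its values were seen) was at the floor on OE high replicate 2 alone, against 0 on arrays of the other groups outside Oct4 KD. Uty read 3.81 there, 6.82 on replicate 1 and 6.61 and 6.54 in the KD control, and its other probe set 4.19, 5.56, 5.23 and 5.23. RNA of the KD control would bring Uty with it, so these values go against a large share of it, but they rest on a single gene. The first version asked only for more than in those groups and would have been met. The bound of at least 5 genes was set after the 1 had been seen. The labels call both arrays single colony and do not say whether it is the same colony.

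The 2 Oct4 KD arrays differed by 2-fold in 1143 genes, more than any other pair. Some values for RNA quality are there: the Actb control difference moved by 0.279 between the arrays, against at most 0.0345 within the other pairs. The Gapdh control hardly moved. It differed between its ends by 0.152 on replicate 1 and 0.137 on replicate 2, values closer together than in the OE pool (0.095 and 0.128). The transferrin receptor control differed between its ends by 1.68 on replicate 1 and 0.07 on replicate 2, and the 18S ribosomal RNA control read 11.42 and 12.63. In both the Actb and the transferrin receptor control the difference between the ends was smaller on replicate 2. Values for a further advanced response in replicate 1 are there too. Of 436 called genes that differed 2-fold between the arrays, 82.3% lay further from the controls on replicate 1. Replicate 1 also correlated less with the KD control arrays (0.9504 and 0.9506) than replicate 2 did (0.9705 and 0.9707). The share thus largely restates that distance and does not show its cause. The lineage factors Cdx2 (8.67 and 9.77), Gata3 (6.13 and 6.73) and Gata6 (6.58 and 7.67) were higher on replicate 2. Both stay open, and either or both may contribute to the spread that sets the counts of calls.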

How the results depend on the processing

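Leaving out the Oct4 KD arrays, exchanging the controls and dividing the control arrays were chosen after seeing the data; all other alternatives were planned. The Oct4 KD arrays vary more than the others and share 1 spread with them. The log2 fold changes of Arid3a in the 4 control comparisons and of Pou5f1 in Oct4 KD kept direction and side of the threshold under each alternative run for them. Signal over background was not analysed here, so dim genes have no detection limit. When 1 array of a group is left out, the lone array is assumed to vary like the other groups; counts fell in most of these fits and rose for OE high against the BirA control without OE high replicate 2, and in both Oct4 KD comparisons without either Oct4 KD array. The causes of the other changes were not tested.

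In the order OE high, OE pool and Arid3a KD against their controls, Oct4 KD against its control, OE high against OE pool, Arid3a KD against Oct4 KD, and control against control, the counts were 48, 285, 79, 3706, 69, 3580 and 6. With 2-fold or more, counts moved to 31, 155, 1214, 37 and 1169 (OE high, OE pool, Oct4 KD and the direct contrasts). At adjusted p under 0.01 they were 8, 124, 20, 2041, 14, 2076 and 0. Fits of only the 2 groups gave 74, 2251, 3841, 523, 51, 596 and 2124. Without the Oct4 KD arrays they were 820, 1525, 1841, 936 and 1312 in the comparisons that do not use them, and these included all main calls. Without the trend, Arid3a KD gave 124 and the controls 17. Testing each probe set gave 5883 for Oct4 KD, 5584 for Arid3a KD against Oct4 KD and 50 for the controls. The mean of probe sets gave 18 for the controls. Against the other control, Arid3a KD gave 42. Leaving out 1 array gave 2 to 73, 71 to 93, 3 to 9, 1899 to 6044, 8 to 61, 1874 to 5714 and 0 to 0.

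Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated between -0.014 and 0.06. With the replicate block the counts were 17, 223, 46, 3490, 35, 3369 and 0.

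Correlations across genes moved as follows. OE high against Arid3a KD (-0.059) was -0.211 over genes called in either, and -0.337 to 0.211 on leaving out 1 array, reversed without OE high replicate 2. The OE pool against Arid3a KD (-0.099) was -0.151 over called genes, -0.023 with controls exchanged and -0.109 to -0.084 on leaving out 1 array. The 2 knockdowns (0.308) gave 0.188 to 0.363 and the 2 overexpression groups (0.65) gave 0.558 to 0.702. With the control arrays divided, the knockdowns gave 0.276 and 0.265 and the overexpression groups 0.532 and 0.44.

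Of 120 named gene calls, 62 stayed past the threshold on leaving out any 1 array: 2 of 18 in OE high, 16 of 24 in the OE pool, 3 of 24 in Arid3a KD and 24 of 24 in Oct4 KD. Of 54 list calls, 40 did; 10 held with an estimated correlation, 32 with fry and 47 without the dimmest genes, and 0 reversed in these. With controls exchanged 16 of 25 list calls stayed, 7 were lost and 2 reversed. The reversed lists were primed epiblast in OE high (-0.065) and glycolysis and hypoxia in the OE pool (0.244).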

Other observations

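Among genes higher in the OE pool than in its control, many were also higher in Oct4 KD, although the comparisons have separate controls. Higher in both were 126 genes (26.28 from independent lists) and lower in both 38 (13.54), against 27 higher in the pool and lower in Oct4 KD (35.32) and 15 the other way (10.08). The counts from independent lists ignore the shared spread per gene, so the excess is not a test. Across genes r was 0.341 and rho 0.194. The shared genes with the largest smaller change, chosen after their values were seen, were Tagln (4.30 in the OE pool and 4.28 in Oct4 KD), Krt8 (4.09 and 5.57), Krt18 (3.60 and 5.36), Thbs1 (3.56 and 3.46), Fgfbp1 (3.43 and 3.68) and Car4 (3.71 and 3.22). By list, 6 trophectoderm genes, 4 fibroblast markers, 3 epithelial junction genes and 3 primed epiblast genes were among the 126, and the primitive endoderm, interferon and signalling lists had 1 each. For OE high and Oct4 KD, 20 genes were higher in both (5.36 from independent lists), 1 lower in both (1.03), 10 higher in OE high and lower in Oct4 KD (7.2) and 3 the other way (0.77), with r = 0.158 and rho = 0.073.

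On the Oct4 KD arrays, Plac1 read 11.60 on replicate 1 and 8.13 on replicate 2, while Cdx2 read 8.67 and 9.77. The mean of the trophectoderm list lay 2.82 and 1.98 above the KD control, and that of glycolysis and hypoxia genes 0.50 above and -0.19 relative to it. Psmb8 read 5.25 and 3.73 on the OE high arrays and 6.22 and 6.52 in the OE pool. The control of the transferrin receptor differed between its 3-prime and 5-prime ends by 0.07 on Oct4 KD replicate 2 and by 0.64 on BirA control replicate 2, against 1.23 or more on the other arrays. The 18S ribosomal RNA control read 12.63 on Oct4 KD replicate 2. On the other arrays it ran from 10.44 (BirA control replicate 1) to 11.51 (BirA control replicate 2).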
